A study of Mus musculus with 16 samples.

How the data were processed

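5-hydroxymethylcytosine (5hmC) was mapped by CMS-IP in CD4 T cells of Foxp3-eGFP reporter mice (C57BL/6, 5 to 6 weeks old, spleen and lymph nodes), per the labels. There were 4 groups with 2 replicates each: sorted naive cells, sorted Treg, iTreg differentiated with TGFβ, and iTreg differentiated with TGFβ, retinoic acid and vitamin C. Every replicate had a pull-down and an input library, 16 in all. Per the labels' protocols, sheared genomic DNA was spiked with amplicons carrying unmodified cytosine or 5hmC, ligated to methylated adaptors, treated with sodium bisulfite and precipitated with serum against CMS. Reads of these amplicons were not used here, so the values are relative within a library and give no total amount of 5hmC.

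The deposited table holds raw counts of reads in 177720 regions, whole numbers per library, on genome build mm9. Per the file headers, the regions are the union of broad MACS2 peaks at a q of 0.01, with the nearest transcript's symbol, the overlapping gene parts and the nearest transcription start. Per the submitters' processing notes, bcl2fastq 2.20.0.442, Trim Galore 0.4.2, SAMtools 1.7 and MACS2 2.1.0.20151222 were used. The aligner, the read counter and whether peaks were called per library or on pooled reads are not given in the sources used here. A region set called mostly in the deeper libraries would favour the sorted cells and hold fewer regions specific to iTreg, which bears on every count of higher and lower regions. Regions had a median width of 745 bp (175 to 128857 bp) and covered 259 Mb, and 111159 of them (62.5%) overlapped a transcript. Coordinates are printed as in the table.

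Pull-down libraries held 1648804 to 9731897 reads in regions and inputs 1028822 to 1563165. The ratio of pull-down to input reads was 1.49 and 1.72 in TGFβ iTreg, 3.88 and 3.14 in RA+VitC iTreg, 4.9 and 6.33 in Treg, and 5.5 and 6.39 in naive cells. A planned log2 ratio of pull-down over input CPM was not used, because both have the same fixed sum over the same regions. This ratio of reads and the share of reads in the tenth of regions with the most reads are given in its place. A region with no read in a library can still stand at up to 3 reads per library at 95% confidence, which is 1.82 and 1.42 CPM in TGFβ iTreg, 0.751 and 0.784 in RA+VitC iTreg, and 0.308 to 0.391 in the sorted cells. Replicate pull-downs varied 1.12 to 1.23 times as much as counting error alone (chi-square over degrees of freedom, regions with at least 20 reads), and replicate inputs 1.00 to 1.01 times.

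Counts of the 8 pull-down libraries were fitted together with edgeR 4.0.16 (R 4.3.3), 1 group term, TMM scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood F test with 4 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 135412 regions. Counts were also summed per symbol over the regions the table assigns to it (15544 symbols, 14952 tested, of which 14710 are current in the gene table used; 14221 regions have no symbol) and tested in the same way; a sum mixes regions that can move in opposite directions. CPM of pull-downs use library sizes scaled by TMM, and those of inputs the plain number of reads in regions. The common biological coefficient of variation was 0.0437 for regions and 0.0274 for genes. The same region test on the 8 inputs served as background. Each of the 6 pairs of groups was compared. Adjusted p-values in the report are edgeR's, apart from those of the gene lists and of Fisher's exact test.

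15 gene lists fixed before the table was read (Treg signature, Treg methylation loci, naive T cell, T cell activation, Th1, Th2, Th17, Tfh, retinoic acid response, TGFβ pathway, DNA methylation machinery, T cell identity, B cell, myeloid and dendritic cell, CD8 and NK cell) were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over all 90 tests. Of these, 17 passed with the preset correlation and 0 with the estimated one (lowest adjusted p 0.67). With 4 residual degrees of freedom the estimated correlation is itself imprecise, so a list that misses the threshold with it is not shown to be unchanged. Counts of members past the threshold are given over all genes and, where they differ, with adjustment over the list alone. Lists of interferon-stimulated, glycolysis and cell cycle genes were added after seeing the data. Gene parts of called regions were compared with all tested regions by Fisher's exact test with Benjamini-Hochberg adjustment. The tested regions were not matched to the called regions on abundance or width. For each library the mean log2 CPM (prior count 2) over regions higher in Treg than in naive cells minus that over regions lower in Treg was computed.

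The genes named follow a rule fixed in advance. It takes, per comparison, the 5 largest and 5 smallest log2 fold changes among genes past the threshold with a mean of at least 100 reads and no overlap of replicates, up to 4 genes per list past the test with the largest change, the 3 largest and 3 smallest regions with a mean of at least 50 reads, and always Foxp3, Ctla4, Il2ra, Ikzf2, Ikzf4 and Tnfrsf18; predicted genes are skipped. Not every gene the rule takes is printed: genes whose call ended or turned under an alternative were mostly left out, and results for a few withheld genes are not reported. For the genes always named, the rule takes the region with the lowest p for Treg against naive cells. The Flicr regions beside Foxp3 were added after their values were seen.

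The code was tested on simulated counts drawn from the real means and library sizes. All groups shared 1 mean profile and 1 common spread, and only 66 or 67 regions or genes were changed per fold. For Treg against naive cells the region test (123310 regions) recovered 11.9%, 47.8% and 90.9% of regions changed 1.5-, 2- and 4-fold with 5 false calls, and the gene test (14781 genes) 73.1%, 94% and 100% with 9 false calls. For RA+VitC iTreg against TGFβ iTreg the shares were 1.49%, 22.4% and 65.2% of regions (123203 run, 3 false calls). For genes they were 46.3%, 76.1% and 97% (14776 run, 6 false calls). In the simulation small changes were thus mostly missed in the shallower libraries. With so few features changed, the adjusted threshold is stricter than with the many calls of the real data. These shares therefore do not give the power of the real tests. A simulated raised list of 30 genes (14952 genes run) had a camera p of 4.24e-05 for Treg against naive cells and 0.00031 for RA+VitC iTreg against TGFβ iTreg with an estimated correlation.

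Alternatives planned in advance were DESeq2 size factors, library size in place of TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 50 reads, only the 2 groups compared, a replicate block, autosomal regions, each library left out in turn, an adjusted p under 0.01, regions overlapping a transcript, and leaving out regions called in inputs. Loess offsets, thinning to equal depth, assignment by nearest transcription start and the Foxp3 sum with Flicr regions were added after seeing the data.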

Results

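The data describe 5-hydroxymethylcytosine (5hmC), the oxidised form of methylated cytosine that TET enzymes make, in mouse CD4 T cells. It was measured by CMS-IP: sodium bisulfite turns 5hmC into cytosine-5-methylenesulfonate (CMS), and an antiserum against CMS pulls down the DNA fragments that carry it. All cells came from spleen and lymph nodes of C57BL/6 mice that report Foxp3, the lineage transcription factor of regulatory T cells (Treg), with green fluorescent protein. The 4 groups were naive T cells, sorted Treg, induced Treg (iTreg) made from naive cells with TGFβ, and iTreg made with TGFβ, retinoic acid (RA) and vitamin C (VitC), called RA+VitC iTreg here. Vitamin C is a cofactor that raises TET activity; RA and VitC were always given together, so their effects cannot be separated. Each group had 2 pull-down and 2 input libraries. The labels do not say that the 2 replicates were separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical.

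Reads were counted in 177720 regions, of which 135412 had enough reads to be tested. Pull-down libraries held 1648804 and 2114056 reads in these regions for TGFβ iTreg, 3996442 and 3828487 for RA+VitC iTreg, 7664194 and 8347328 for Treg, and 7773777 and 9731897 for naive cells. Inputs held 1028822 to 1563165. The tenth of regions with the most reads took 53.9% and 55.9% of the pull-down reads in TGFβ iTreg, 59.8% and 59.1% in RA+VitC iTreg, 53.7% and 54.3% in Treg, 55.1% and 55.4% in naive cells, and 40.5% to 40.9% in inputs. Inputs served as background. The same test called at most 3 of 44917 input regions in any of the 6 comparisons, with 2205 to 2622 at an unadjusted p under 0.05. Values per gene are reads summed over the regions the deposited table assigns to that gene, in CPM, which scales out library size, and describe 5hmC enrichment, not expression. Genes called well covered below have a mean of at least 100 reads and no overlap between the replicates of the 2 groups compared, with predicted genes left out.

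**Figure D1:**
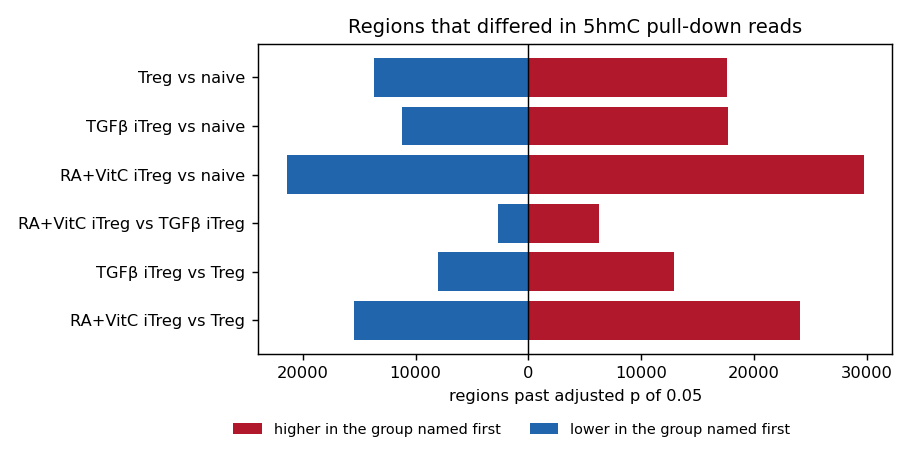
Number of regions (horizontal axis) past an adjusted p of 0.05 in edgeR's quasi-likelihood test in each of the 6 comparisons. Red bars count regions higher in the group named first and blue bars regions lower in it; RA+VitC iTreg against naive cells gave the most calls, 29718 higher and 21405 lower.

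The comparison of sorted Treg with naive cells asks where 5hmC differs between these 2 sorted populations. Per the labels, naive cells were sorted as CD4+eGFP-CD25-CD62LhiCD44lo and Treg as CD4+eGFP+. Differences over Il2ra, which encodes CD25, and over activation and naive genes can therefore follow in part from the gates. Treg carried 3.91-fold more 5hmC reads than naive cells over Ikzf2, which encodes the transcription factor Helios (1380 ± 7.2 CPM in Treg, SD, n = 2; log2 fold change 1.97, SE 0.04, adjusted p = 2.1e-74). Il2ra, the high-affinity IL-2 receptor chain, was 2.33-fold higher (log2 1.22, SE 0.05), and Foxp3 2.38-fold higher as the table assigns its regions (log2 1.25, SE 0.11, adjusted p = 1e-18). With the neighbouring Flicr regions, added after their values were seen, the Foxp3 sum was 0.58 higher on the log2 scale (SE 0.09). The well-covered genes with the largest increases included Timd2 (log2 2.26), Prr5l, a component of the mTORC2 complex (2.18), and Itgb8, an integrin chain that activates latent TGFβ (2.07). The largest decreases among well-covered genes were over Pdzrn3 (log2 -2.22), Nacc2 (-2.17), App, the amyloid precursor (3.99-fold lower), Dmbt1 (-1.91) and Hs3st3b1 (-1.87). Among well-covered genes Stk31 had the largest value (log2 2.87), which came from regions outside its transcript, since regions that overlap the transcript gave -0.48 (adjusted p = 0.52).

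Within single loci the Treg gain was uneven. For Ikzf2, Il2ra, Ctla4 and Ikzf4 the region named is the one with the lowest p in this comparison. At Ikzf2, 41 of 52 regions rose and 2 fell, and the region at 1:69624171 to 69648754 (mm9), which covers exon and intron sequence, was 3.24 log2 units higher (SE 0.09). At Il2ra, 4 of 7 regions rose and 1 fell, and the region at 2:11597273 to 11619124, over exon, intron and 3′ UTR, rose by 2.52 (SE 0.10). All 11 Ctla4 regions were tested and 8 rose. The intergenic region upstream of it at 1:60925009 to 60934834 rose by 1.02 (SE 0.09). Ikzf4 (Eos) rose over its promoter and 5′ UTR at 10:128074640 to 128082643 (0.93, SE 0.10), and Tnfrsf18 (GITR) rose by 0.47 as a gene (SE 0.08). The region over Rgs1, a regulator of G-protein signalling, at 1:146088534 to 146094741 (exon, intron and 3′ UTR) had the largest gain of all regions named by the fixed rule in this comparison (log2 3.54, SE 0.17, adjusted p = 4.8e-90). Intronic regions of Myo1e at 9:70059008 to 70070729 and 9:70096031 to 70103009 rose by 3.45 and 3.30. A Vwf region at 6:125627222 to 125630948 (exon and intron) was lower by a log2 value of -2.71 (SE 0.20).

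By gene group, the Treg signature rose: 29 of 33 measured members were higher and 0 lower, over all genes and when adjusted over the list alone (camera adjusted p = 1.1e-15; adjusted p = 0.67 with an estimated correlation). Lad1 (log2 3.05, SE 0.51), Itgb8, Ikzf2 and the inhibitory receptor Klrg1 (1.94, SE 0.11) led it. All 6 loci known to be demethylated in Treg rose as gene sums (camera adjusted p = 2e-05, and 0.67 with an estimated correlation). For Foxp3 the sum covers its 3′ part only. The 5′ part of Foxp3, assigned to Flicr and singled out after its values were seen, was lower in Treg (log2 -0.95, edgeR adjusted p = 3.5e-06). T cell activation genes were higher in 18 of 32 and lower in 2, adjusted over the list alone too, with Bhlhe40 (1.29), Il2rb (1.27), Rel (1.18) and Batf (0.92) at the top (adjusted p = 0.00014; adjusted p = 0.67 with an estimated correlation). Genes of naive T cells fell in 16 of 21 members with 0 rising, the same adjusted over the list alone: Igfbp4 (-1.57), the IL-7 receptor Il7r (-0.66), Dapl1 (-0.55) and the chromatin organiser Satb1 (-0.44) led them (adjusted p = 2.6e-05; adjusted p = 0.82 with an estimated correlation). T cell identity genes fell in 18 of 23 with 0 rising, again the same over the list alone, among them the CD3 chain genes Cd3g (-0.50) and Cd3e (-0.36) (adjusted p = 0.001; adjusted p = 0.82 with an estimated correlation). Th2 genes rose in 9 of 14 and fell in 1 (2 adjusted over the list alone), with Maf (1.26) and Nfil3 (0.90) leading (adjusted p = 0.01; adjusted p = 0.82 with an estimated correlation; 0.0505 thinned to equal depth).

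The other lists did not pass as groups. Th17 genes rose in 7 of 14 and fell in 2 (9 and 2 adjusted over the list alone), with the chemokine receptor Ccr6 (1.52) and Il22 (1.08) highest (adjusted p = 0.13). Th1 genes rose in 7 of 16 and fell in 4 (7 and 5 over the list alone), including Tbx21, which encodes T-bet (1.06; list adjusted p = 0.30). Tfh genes rose in 5 and fell in 2 of 12 (adjusted p = 0.37), and Il21 was lower (-0.58). Retinoic acid response genes rose in 7 and fell in 3 of 23 (adjusted p = 0.52), with the receptor gene Rarg at 1.04. TGFβ pathway genes went both ways, 9 up and 9 down of 26 (adjusted p = 0.69), from Itgb8 and Tgif1 (1.42) to Tgfbr3 (-0.83). DNA methylation machinery genes rose in 11 and fell in 5 of 24 (adjusted p = 0.11), and Tet2 rose by 0.74 (SE 0.05). For these 4 lists the counts adjusted over the list alone were the same. Markers of other cell types also moved. CD8 and NK cell genes rose in 3 and fell in 7 of 11, with Klrd1 (-1.27), Prf1 (-1.21) and Klra1 (-1.16) lowest (adjusted p = 0.073). Myeloid and dendritic genes rose in 2 and fell in 3 of 14, Zbtb46 at 1.08 and Flt3 at -0.75 (adjusted p = 0.50, list median -0.13 against a mean of 0.04). B cell genes rose in 5 and fell in 0 of 14 (adjusted p = 0.25), where the calls of Blk, Blnk, Pax5 and Spib were lost with DESeq2. The counts adjusted over the list alone were the same for these 3.

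In total 17611 regions were higher and 13710 lower in Treg (edgeR, adjusted p under 0.05), as were 2994 and 2867 of 14952 genes. DESeq2 called 5616 and 2390 regions and 1805 and 1443 genes. Leaving out 1 library gave 11308 and 8471 regions without naive replicate 1, 10131 and 7232 without naive replicate 2, 11358 and 8156 without Treg replicate 2, and 9098 lower without Treg replicate 1.

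TGFβ iTreg were compared with naive cells, the kind of cell they were differentiated from. No group was cultured without TGFβ. For both kinds of iTreg, effects of culture and activation therefore cannot be told apart from those of iTreg differentiation. The strongest 5hmC gains among well-covered genes were over Cacng6, a calcium channel subunit gene (40.6-fold, log2 5.34, SE 0.18, adjusted p = 2.3e-56, n = 2), the homeobox gene Pitx1 (32.8-fold), Stfa3 (28.9-fold), the cytokine receptor gene Lifr (18-fold) and Tmem252 (17.1-fold). Among Treg genes, Socs2 rose 11.1-fold, Lrrc32, whose product docks latent TGFβ, 7.6-fold, Il2ra 6.74-fold and Ctla4 3.86-fold. The Th17 cytokine gene Il17a rose 19.8-fold (27.9 ± 11 CPM; log2 4.31, SE 0.32) and Ccl20, the ligand of CCR6, 20.8-fold (log2 4.38, SE 0.31). The largest losses among well-covered genes were over Isg15, an interferon-induced ubiquitin-like protein (log2 -1.76), Mettl7b (-1.34), Cd8b1 (-1.32), Irf9 (-1.31) and Hsdl1 (-1.29).

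The Foxp3 locus differed along the gene. Its 3′ part (X:7163959 to 7172345), which the deposited table assigns to Foxp3, stood at 17.4 ± 4.4 CPM in TGFβ iTreg against 15.7 ± 1.8 in naive cells, a log2 difference of 0.16 (adjusted p = 0.66). The TGFβ iTreg inputs stood at 14.4 ± 3.8 CPM there. The 5′ part (X:7156699 to 7163183), which overlaps the Foxp3 promoter, 5′ UTR, exon and intron but which the table assigns to the neighbouring non-coding RNA gene Flicr, stood at 113 ± 23 CPM against 12.2 ± 1.1 in naive cells and 6.28 ± 1.5 in Treg (log2 3.22 over naive, adjusted p = 2.9e-127). In Treg the 5′ part was lower than in naive cells (-0.95, adjusted p = 3.5e-06), with inputs at 14.5 ± 1.2 and 10.5 ± 2.8 CPM. Pull-down and input CPM have the same fixed sum over regions, so input CPM give no background level for either part. Whether the Treg and naive pull-downs stood above background at the 5′ part cannot be told. The 3′ part was higher in Treg (37.0 ± 3.2 CPM; log2 1.23, SE 0.12). The 5′ part and the region upstream were singled out after their values were seen.

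**Figure D2:**
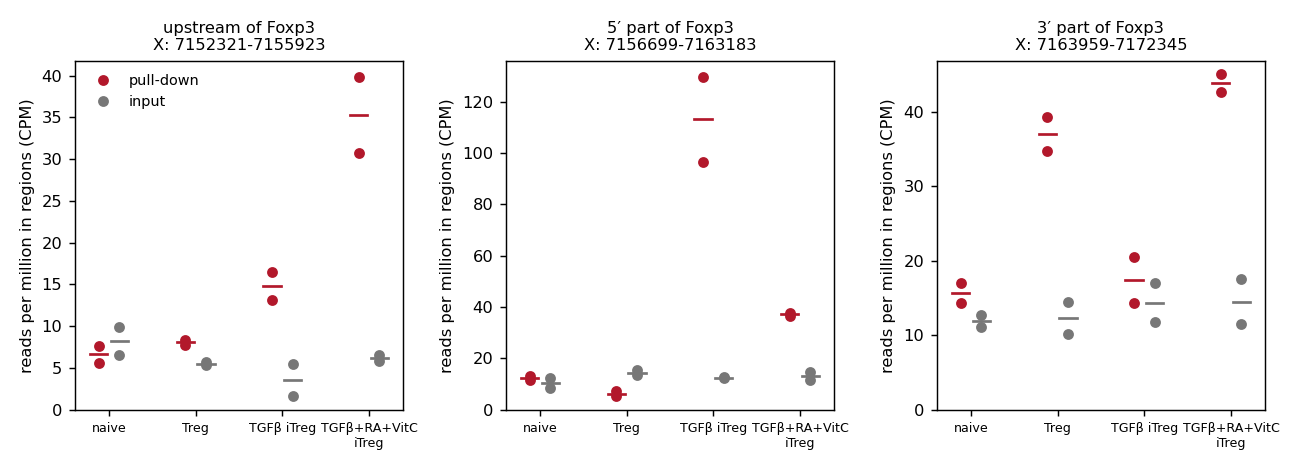
CPM of region reads (vertical axis) for 3 neighbouring regions of the Foxp3 locus on chromosome X (mm9). Points are libraries and short lines group means; red is the 5hmC pull-down and grey the input. The 5′ part is highest in TGFβ iTreg (113 CPM) and the 3′ part in RA+VitC iTreg (43.9 CPM) and Treg (37.0 CPM).

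Treg signature genes rose in 28 of 33 measured members and 1 fell, also when adjusted over the list alone (camera adjusted p = 4.9e-11; adjusted p = 0.67 with an estimated correlation). Of the 6 Treg methylation loci 5 rose, all except Foxp3 as the table assigns it, whose sum with the Flicr regions rose by 2.11 (adjusted p = 0.001; adjusted p = 0.82 with an estimated correlation). Activation genes rose in 20 of 32 and fell in 3, the same over the list alone, with Bhlhe40 (2.05), Il2rb (1.93) and Hif1a (1.15) among them (adjusted p = 2e-04; adjusted p = 0.67 with an estimated correlation). Th2 genes rose in 8 of 14 and fell in 2, including Il24 (3.08), Ccr3 (2.79) and Nfil3 (1.87) (adjusted p = 0.016; adjusted p = 0.82 with an estimated correlation; 0.0546 with a mean of at least 50 reads). T cell identity genes fell in 15 of 23 and rose in 3: Cd3g fell by 1.17, Cd6 by 1.06 and Cd4 by 0.70 on the log2 scale (adjusted p = 0.0054; adjusted p = 0.82 with an estimated correlation). Th17 genes rose in 8 and fell in 3 of 14 (4 adjusted over the list alone), with Il17f (2.66) and Ccr6 (2.46) beside Il17a and Ccl20. The list did not pass (adjusted p = 0.17). The lists of naive T cell, retinoic acid response and TGFβ pathway genes did not pass either (adjusted p of 0.38, 0.69 and 0.78). The retinoic acid list had a median of -0.09 and a mean of 0.25, with the test upwards. Myeloid and dendritic genes rose in 5 and fell in 3 of 14, with the G-CSF receptor gene Csf3r at 2.02 and Zbtb46 at 1.53 (adjusted p = 0.21). CD8 and NK genes rose in 2 and fell in 6 of 11, Cd8b1 and Cd8a (-1.26) among the latter (3 and 6 over the list alone; adjusted p = 0.19). B cell genes rose in 4 and fell in 2 of 14 (adjusted p = 0.80; median -0.21, mean 0.06, test downwards).

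Regions higher in TGFβ iTreg than in naive cells numbered 17693 and regions lower 11213. Higher regions lay more often between genes, 45.7% against 36.3% of tested regions (Fisher's exact test, odds ratio 1.57, 95% interval 1.52 to 1.62). Lower regions lay more often on a 5′ UTR, 10.6% against 4.98% (odds ratio 2.52, 2.36 to 2.70). Of the lower regions, 6744 were among the 27083 most abundant tested regions, as were 5473 of the higher regions. Called and tested regions were not matched on abundance or width. A link with gene parts therefore cannot be told apart from a link with abundance or width. The intronic Gldc region at 19:30236717 to 30239716 rose from 0.757 ± 0.2 to 46.4 ± 4.9 CPM (log2 5.93, SE 0.27), and the intergenic region at 13:18764831 to 18769427, assigned to Vps41, from 1.14 ± 0.71 to 61.4 CPM (log2 5.65). Genes higher were 3496 and lower 2720, and 3199 and 3239 with library size in place of TMM scaling. DESeq2 called 3938 regions lower, and edgeR called 5516 lower without TGFβ iTreg replicate 1 and 10023 higher and 6086 lower without TGFβ iTreg replicate 2.

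In RA+VitC iTreg against naive cells 29718 regions were higher and 21405 lower. These libraries held more reads than those of TGFβ iTreg. Thinned to equal depth, chosen after seeing the data, 11368 were higher and 7251 lower, against 9740 and 5407 for TGFβ iTreg against naive cells. Over Treg genes, Socs2 rose 18.8-fold (log2 4.23, SE 0.08, n = 2), Lrrc32 10.3-fold, Il2ra 8.22-fold and Rgs1 5.39-fold. Foxp3 rose 2.68-fold (43.8 ± 1.4 CPM; log2 1.42, SE 0.13, adjusted p = 1.4e-18). Cacng6 (37.5-fold), Pitx1 (27.4-fold), Stxbp6 (22-fold) and Pou5f1-rs4 (18.5-fold) had the largest gains among well-covered genes beside Socs2. Losses among well-covered genes were largest over G6pc, the glucose-6-phosphatase gene (log2 -2.08), Isg15 (-2.04), Pja1 (-1.96), the NK receptor gene Klra1 (-1.96) and Uox, the urate oxidase gene (-1.78).

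Treg signature genes rose in 29 of 33 and fell in 1 (adjusted p = 2.6e-11; adjusted p = 0.67 with an estimated correlation) and all 6 Treg methylation loci rose (adjusted p = 0.00022; adjusted p = 0.82 with an estimated correlation), with the same counts adjusted over the list alone. Of 32 activation genes 23 rose and 3 fell (24 and 3 adjusted over the list alone), led by Bhlhe40 (2.27), Il2rb (4-fold) and the transferrin receptor Tfrc (1.55) (adjusted p = 0.00019; adjusted p = 0.67 with an estimated correlation). Genes of naive T cells went both ways, 11 up and 7 down of 21, from Treml2 (1.30) to Satb1 (-1.06) (11 and 8 over the list alone; adjusted p = 0.80). TGFβ pathway genes rose in 13 and fell in 7 of 26, with Pmepa1, a feedback inhibitor of TGFβ signalling, 3.13-fold higher (13 and 8 over the list alone; adjusted p = 0.26). Retinoic acid response genes rose in 13 and fell in 5 of 23 (adjusted p = 0.21). DNA methylation machinery genes rose in 11 and fell in 5 of 24, among them Mbd1 (1.83) and Uhrf2, whose product binds 5hmC (1.12; 12 and 5 over the list alone; list adjusted p = 0.30). Cd8b1 (-1.69), Cd8a (-1.48) and Prf1 (-1.37) were among 6 of 11 CD8 and NK genes that fell, with 1 rising (3 up and 6 down over the list alone; adjusted p = 0.077). Myeloid genes rose in 7 and fell in 3 of 14, Adgre1 at 2.21 and Flt3 at -1.55 (adjusted p = 0.52). B cell genes rose in 3 and fell in 5 of 14, Bank1 at 1.02 (adjusted p = 0.50).

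Of the genes tested, 4367 were higher and 3972 lower. With library size in place of TMM scaling, 42% of called regions and 38.8% of called genes were higher, against 58.1% and 52.4%, and with DESeq2 7010 regions were lower. Regions lower numbered 11328 without RA+VitC iTreg replicate 1 and 12573 without replicate 2.

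The direct comparison of the 2 kinds of iTreg asks what adding RA and VitC to TGFβ does to 5hmC. The sorting or differentiation labels of both iTreg groups name no eGFP gate, so they do not give the share of cells with Foxp3. Differences in that share cannot be told apart from differences within cells, here or against sorted Treg. At Il2ra both directions occurred in 1 gene: the region over the promoter, 5′ UTR, exon and intron (2:11563877 to 11567653) stood at 74.2 ± 8 CPM in TGFβ iTreg and 11.7 ± 1.3 in RA+VitC iTreg (log2 -2.67, SE 0.18, adjusted p = 4e-47, n = 2), against 2.86 ± 1.2 in Treg and 4.68 ± 0.81 in naive cells. The Il2ra region over exon, intron and 3′ UTR (2:11597273 to 11619124) was in turn higher with RA+VitC (1.19, SE 0.10, adjusted p = 7.4e-30). Foxp3 behaved alike: with RA+VitC the 5′ part was lower (37.1 ± 0.74 against 113 ± 23 CPM; log2 -1.62, adjusted p = 4.7e-33), the 3′ part higher (43.9 ± 1.7 against 17.4 ± 4.4 CPM; 1.32, adjusted p = 3.4e-09), and the region upstream of the gene (X:7152321 to 7155923) higher (35.3 ± 6.4 against 14.8 ± 2.4 CPM; 1.24, adjusted p = 4.9e-07). The Foxp3 sum as the table assigns it therefore rose (log2 1.23), while the sum with the Flicr regions fell (-0.42, SE 0.10, adjusted p = 0.00028). The Il2ra gene sum (0.29) was not past the threshold when regions were assigned by nearest transcription start (0.11) or with loess offsets (0.10), both chosen after seeing the data.

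Il17a carried 9.15-fold fewer reads in RA+VitC iTreg (3.1 ± 0.15 against 27.9 ± 11 CPM; log2 -3.19, SE 0.34, adjusted p = 2e-14). DESeq2 gave no adjusted p for it. The largest losses among well-covered genes were over Rtn1 (-1.92), Nacc2 (-1.90), Eps8l3 (-1.82), the metalloprotease gene Mmp25 (-1.65) and the magnesium channel gene Trpm6 (-1.56). The largest gains among them were over Zscan29 (1.54), Trpc4ap (1.44), the laminin gene Lamc1 (1.38), Pmepa1 (1.37) and Enpp4 (1.34). The Lamc1 intron region at 1:155175189 to 155178986 rose from 12.3 ± 1.2 to 63.6 ± 9.6 CPM (log2 2.38, SE 0.20). The Bckdhb intron region at 9:83915006 to 83916177 fell from 65 ± 2.6 to 11.8 ± 1.5 CPM (log2 -2.46, SE 0.18). Higher regions lay on a 5′ UTR in 12% of cases against 4.98% of tested regions (odds ratio 2.81, 95% interval 2.59 to 3.04) and on an exon in 34.1% against 23% (1.79, 1.69 to 1.89). Lower regions lay between genes in 47.4% against 36.3% (1.60, 1.48 to 1.72). Of the 27083 most abundant tested regions, 4298 were higher and 1059 lower. Abundance and width were not matched here either, so these shares cannot be told apart from a link with abundance or width.

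**Figure D3:**
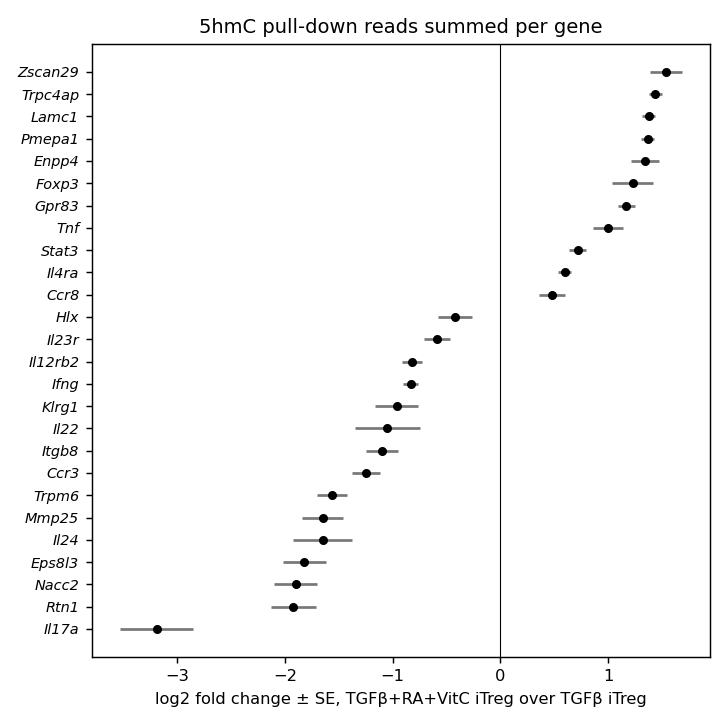
Log2 fold change of 5hmC pull-down reads summed per gene in RA+VitC iTreg over TGFβ iTreg (horizontal axis, points, with SE bars) for genes named by the fixed rule, 2 libraries per group. Il17a is lowest (-3.19) and Zscan29 highest (1.54).

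T cell identity was the list that passed: 11 of 23 genes rose and 0 fell (13 and 1 adjusted over the list alone), with Runx1 (0.67), Lck (0.48), Cd6 (0.48) and Lat (0.46) leading (camera adjusted p = 0.0051; adjusted p = 0.82 with an estimated correlation). Without TGFβ iTreg replicate 1 the list's adjusted p was 0.11. Treg signature genes rose in 15 and fell in 8 of 33 (16 and 8 over the list alone), from Foxp3 (1.23) and Gpr83 (1.17, SE 0.08) to Itgb8 (-1.10) and Klrg1 (-0.96). The list did not pass (adjusted p = 0.21). Of the 6 Treg methylation loci 5 rose and 0 fell, with Foxp3 counted by its 3′ part alone (camera adjusted p = 0.064). Ikzf4 rose by 0.47, the sums of Ikzf2 (0.16) and Ctla4 (0.14) turned to -0.062 and -0.043 with loess offsets, and Tnfrsf18 stood at -0.02. Both the Ikzf2 and the Ctla4 call were also lost with library size in place of TMM (0.057 and 0.034) and with only the 2 groups compared. Ctla4 further lost its call with DESeq2 and with a mean of at least 50 reads, and stood at -0.064 over transcript regions. Genes of naive T cells rose in 11 and fell in 5 of 21 (11 and 6 over the list alone; adjusted p = 0.16), with Treml2 (0.99), Foxp1 (0.76) and Bach2 (0.67), both transcription factors of resting T cells, highest. TGFβ pathway genes rose in 12 and fell in 4 of 26 (12 and 5 over the list alone; adjusted p = 0.11), with the inhibitors Pmepa1, Skil (0.78) and Ldlrad4 (0.76) up. Activation genes rose in 10 and fell in 3 of 32 (12 and 5 over the list alone; adjusted p = 0.21), Nfatc1 at 0.49.

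Helper lineage genes moved unevenly. Th1 genes rose in 3 and fell in 5 of 16, with Tnf at 1.00, Ifng at -0.83 (its call was lost over transcript regions alone) and the IL-12 receptor gene Il12rb2 at -0.82 (adjusted p = 0.83; median 0.03, mean -0.05). Th2 genes rose in 2 and fell in 3 of 14 (5 adjusted over the list alone), from Il4ra (0.60) to Ccr3 (-1.25) and Il24 (-1.65) (adjusted p = 0.19). Th17 genes rose in 4 and fell in 6 of 14 (5 and 6 over the list alone; adjusted p = 0.80), with Stat3 at 0.72 and the IL-23 receptor gene Il23r at -0.59. Tfh genes rose in 2 and fell in 5 of 12, Cxcr5 at 0.38 and Tox2 at -0.71 (adjusted p = 0.37). Retinoic acid response genes did not move as a group, 7 up and 5 down of 23 (adjusted p = 0.61). Dhrs3, a retinaldehyde reductase induced by RA, rose by 0.98 (SE 0.14), and Gpr15, a gut-homing receptor, was at -1.24 (SE 0.11). DNA methylation machinery genes rose in 6 and fell in 4 of 24 (8 and 5 over the list alone; adjusted p = 0.45), with Uhrf2 at 0.85, Mbd1 at 0.59 and Dnmt3a at 0.49. CD8 and NK genes fell in 4 of 11 and rose in 0 (adjusted p = 0.055). Myeloid and dendritic genes rose in 1 and fell in 5 of 14 (1 and 6 over the list alone; adjusted p = 0.20). B cell genes rose in 1 and fell in 2 of 14 (0 and 2 over the list alone; adjusted p = 0.43).

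Altogether 6227 regions were higher and 2682 lower, 69.9% higher, and 1853 genes were higher and 1605 lower, 53.6% higher. This split depended on scaling, on the filter and on the fit: 43.2% of called regions were higher with library size in place of TMM (3515 against 4627; 33.3% of genes, 1200 of them higher), 49% with a mean of at least 50 reads (2786 against 2900), 55% with loess offsets and 53.8% with only these 2 groups in the fit. DESeq2 called 3656 and 1010 regions and 1055 genes lower. Regions higher and lower were 3300 and 1531 without TGFβ iTreg replicate 1 and 3979 and 1164 without RA+VitC iTreg replicate 1. Lower regions were 912 without TGFβ iTreg replicate 2 (genes lower 972) and 1375 without RA+VitC iTreg replicate 2.

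Set against sorted Treg, both kinds of iTreg carried less 5hmC summed over Ikzf2 and more summed over Il2ra and Ctla4. Ikzf2 as a gene was lower in TGFβ iTreg (log2 -0.69, SE 0.05, adjusted p = 1.8e-26, n = 2) and in RA+VitC iTreg (-0.52, SE 0.04). Of its 52 tested regions, 17 were lower and 4 higher in TGFβ iTreg, and 19 were lower and 10 higher in RA+VitC iTreg. Its exon and intron region at 1:69624171 to 69648754 had values of -2.02 and -1.92. That region was picked for its difference between Treg and naive cells, which favours a lower value in iTreg than in Treg. Il2ra was 2.9-fold higher in TGFβ iTreg and 3.53-fold higher in RA+VitC iTreg, and Ctla4 2.31-fold and 2.54-fold. The Foxp3 3′ part was lower in TGFβ iTreg (-1.07, adjusted p = 2.4e-07) and at 0.24 in RA+VitC iTreg (adjusted p = 0.11). The 5′ part was higher in both (4.17 and 2.55), so that the sum with the Flicr regions was higher in TGFβ iTreg (1.53) and in RA+VitC iTreg (1.11), although the Foxp3 sum as the table assigns it was lower in TGFβ iTreg (-1.06). Pitx1 (4.63 and 4.37) and Cacng6 (12.1-fold and 11.2-fold) were higher in both.

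In TGFβ iTreg against Treg, 17 of 33 Treg signature genes were higher and 8 lower (adjusted p = 0.14). Of 21 genes of naive T cells 13 were higher and 5 lower (adjusted p = 0.15), with Il7r at 0.70. The Th17 genes Il17a (36-fold) and Ccl20 (8.3-fold) were higher in a list that did not pass (adjusted p = 0.61). Egr1 (-1.06) and the methyltransferase gene Dnmt3a (-0.69) were lower. Myeloid and dendritic genes were higher in 5 of 14 and lower in 0, with Csf3r at 2.37 and Spi1, which encodes PU.1, at 0.99 (adjusted p = 0.086). In RA+VitC iTreg against Treg, 24 of 33 Treg signature genes were higher and 8 lower (adjusted p = 0.0058; adjusted p = 0.82 with an estimated correlation). Of 21 genes of naive T cells 15 were higher and 1 lower (2 adjusted over the list alone; adjusted p = 0.0066; adjusted p = 0.82 with an estimated correlation), among them Treml2 (3.25-fold), Txk (1.14) and Foxp1 (0.81). Socs2 was 6.27-fold higher, Klrg1 (-1.85) and Itgb8 (-1.69) lower, and the activation genes Tfrc (1.34), Gzmb (1.21) and Nfatc2 (1.00) higher. Counts adjusted over the list alone were the same for the lists in this paragraph where none is given. Cd8b1 was lower than in Treg in both iTreg groups (-1.12 and -1.48).

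Against Treg, 12935 regions were higher and 7966 lower in TGFβ iTreg, and 24114 higher and 15459 lower in RA+VitC iTreg. Genes were 3104 and 2251, and 3981 and 3455. For TGFβ iTreg, library size in place of TMM gave 2753 genes higher and 2916 lower. For RA+VitC iTreg it gave 39% of called regions higher against 60.9% (28306 lower) and 35.6% of genes against 53.5% (5339 lower), and DESeq2 gave 15163 higher and 4084 lower regions and 2150 lower genes. For TGFβ iTreg DESeq2 gave 2469 lower regions and 1407 lower genes. Without TGFβ iTreg replicate 1 the TGFβ iTreg comparison gave 3604 lower regions and without replicate 2 6902 higher and 3887 lower. The RA+VitC iTreg comparison gave 6927 lower regions without RA+VitC iTreg replicate 1 and 8242 without replicate 2.

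Regions called in Treg against naive cells were then read in the iTreg libraries, whose groups were not part of that contrast. The gap between Treg and naive cells is fixed by construction, since the regions were called on the libraries of these 2 groups. As no group was cultured without TGFβ, the distance of iTreg from naive cells cannot be ascribed to differentiation alone. Background reads, which move a library towards the inputs, could also add to that distance. The mean log2 CPM over Treg-higher regions minus that over Treg-lower regions was -1.83 in naive cells (SD 0.0092, n = 2), -0.35 in TGFβ iTreg (SD 0.011), -0.13 in RA+VitC iTreg (SD 0.037) and 0.06 in Treg (SD 0.011), against -0.30 in the inputs of every group. RA+VitC iTreg lay 0.223 above TGFβ iTreg, 6 times the larger within-group SD; 2 libraries against 2 cannot give an exact two-sided permutation p below 0.33. Of the regions higher with RA+VitC than with TGFβ alone, 1655 were also higher in Treg than in naive cells (809.9 for independent lists; Fisher's exact odds ratio 2.57, 95% interval 2.42 to 2.72). Likewise 576 of the lower regions were lower in Treg (271.5 for independent lists; 2.49, 2.26 to 2.74). Opposite directions numbered 762 and 523, against 630.5 and 348.8 for independent lists. Of the 3516 regions called in both comparisons, 63.5% shared a direction. The values for independent lists were not matched on abundance. The 27083 most abundant regions held 4298 higher and 1059 lower regions for RA+VitC against TGFβ iTreg. For Treg against naive cells they held 4830 higher and 5951 lower. Part or all of an excess over independent lists can therefore come from a shared link with abundance, which was not tested. The log2 fold changes over all regions correlated at r = 0.081, across regions, which are not independent replicates.

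**Figure D4:**
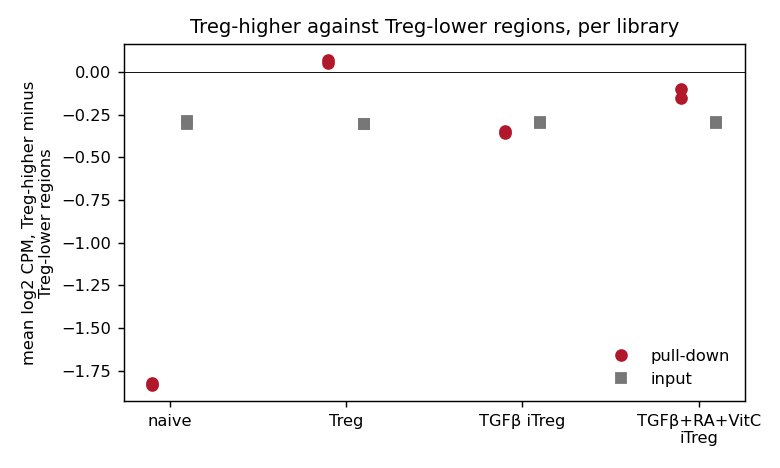
Mean log2 CPM over regions higher in Treg than naive cells minus the mean over regions lower in Treg (vertical axis), per library and group. Circles are pull-downs and squares inputs; naive pull-downs lie near -1.83, RA+VitC iTreg near -0.13, TGFβ iTreg near -0.35 and all inputs near -0.30.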

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

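Loess offsets, thinning of all pull-downs to 1648804 reads, assignment by nearest transcription start and the Foxp3 sum with Flicr regions were chosen after seeing the data; the other alternatives were planned. All 27 results that answer a comparison stayed within 1.5 times, or within the spread between replicates, with DESeq2 size factors in the edgeR fit, without a filter on low counts, with only the 2 groups compared and with autosomal regions only, as did all those run with regions overlapping a transcript, without regions called in inputs, with an adjusted p under 0.01 or by nearest transcription start. Where nothing else is said below, the cause was not tested. Camera was not run with the DESeq2 test, with only the 2 groups compared or with loess offsets. The iTreg pull-downs held the fewest reads. Simulated 2-fold changes were recovered in 22.4% of regions for RA+VitC iTreg against TGFβ iTreg and in 47.8% for Treg against naive cells. Few regions were changed in that simulation, so these shares do not give the power of the real tests.

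With library size in place of TMM, the median log2 fold change of all regions and genes moved to -0.26 and -0.17 for RA+VitC iTreg against naive cells, -0.17 and -0.11 against TGFβ iTreg and -0.30 and -0.18 against Treg. Lower regions became 33394 against naive cells, 4627 against TGFβ iTreg (3515 higher, 1200 genes higher) and 28306 against Treg (5339 genes lower). Genes became 3199 higher and 3239 lower for TGFβ iTreg against naive cells and 2753 and 2916 against Treg. Loess offsets moved the region medians of TGFβ iTreg against naive cells and against Treg to -0.14. Over the regions called with loess offsets, the axis difference of RA+VitC and TGFβ iTreg was 0.269. In every alternative the axis was scored on log2 CPM scaled by TMM. The scaling alternatives therefore changed only which regions were called, and none shows the axis with the abundance trend removed.

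The DESeq2 Wald test called fewer: 5616 regions higher and 2390 lower (1805 and 1443 genes) for Treg against naive cells; 3938 lower for TGFβ iTreg and 7010 lower for RA+VitC iTreg against naive cells; 3656 higher and 1010 lower (1055 genes lower) for RA+VitC against TGFβ iTreg; 2469 lower (1407 genes lower) for TGFβ iTreg and 15163 higher and 4084 lower (2150 genes lower) for RA+VitC iTreg against Treg. With a mean of at least 50 reads fewer regions are tested, by construction, and 5640 were higher and 4944 lower for Treg, 6351 and 4890 for TGFβ iTreg and 8006 and 7654 for RA+VitC iTreg against naive cells, 2786 higher and 2900 lower for RA+VitC against TGFβ iTreg, and 5718 and 4249 for TGFβ iTreg and 7329 and 6912 for RA+VitC iTreg against Treg. Thinned to equal depth, with fewer reads by construction, 3144 regions were higher and 1971 lower (1361 and 1216 genes) for Treg, 9740 and 5407 for TGFβ iTreg and 11368 and 7251 (2495 genes lower) for RA+VitC iTreg against naive cells, 3160 higher for RA+VitC against TGFβ iTreg, and 7983 and 3996 for TGFβ iTreg and 9396 and 5258 (2626 and 1994 genes) for RA+VitC iTreg against Treg.

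The replicate block, with the numbers of the sorted cells and the title marks of the iTreg libraries as pairing, changed none of the 11 results it covers: 16969 regions were higher and 13112 lower (3027 and 2916 genes) for Treg against naive cells and 5899 and 2495 (1869 and 1613 genes) for RA+VitC against TGFβ iTreg, the axis difference was 0.227 and the odds ratios of the overlap 2.67 and 2.59. Deviations of same-numbered libraries correlated at 0.0081 and 0.0052. Replicates varied only 1.12 to 1.23 times as much as counting error, so most of each deviation is counting error. The correlations therefore cannot show whether the libraries were paired.

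Leaving out 1 library leaves a group with 1 sample, which is assumed to vary like the others. Calls fell when the library belonged to a compared group, and rose or fell when it did not. Regions higher ranged from 10131 to 18682 and lower from 7232 to 14354 for Treg against naive cells (genes 2309 to 3123 and 1981 to 2962), 10023 to 15212 and 5516 to 9335 for TGFβ iTreg (2543 to 3200 and 1872 to 2424) and 23250 to 24358 and 11328 to 17384 for RA+VitC iTreg against naive cells (3778 to 3995 and 3129 to 3531). They ranged from 3300 to 5824 and 912 to 2957 for RA+VitC against TGFβ iTreg (1280 to 1863 and 972 to 1630), 6902 to 11469 and 3604 to 6876 for TGFβ iTreg against Treg (2173 to 2875 and 1505 to 2077) and 17523 to 19657 and 6927 to 12876 for RA+VitC iTreg against Treg (3334 to 3661 and 2511 to 3045). The axis difference ranged from 0.19 to 0.248 and the overlap odds ratios from 2.73 to 3.75 for higher and 2.59 to 2.85 for lower regions.

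Of 17 gene list calls with the preset correlation, all 17 were lost with the estimated one; with a mean of at least 50 reads the Th2 list in TGFβ iTreg against naive cells (adjusted p = 0.0546), thinned the Th2 list in Treg against naive cells (0.0505) and without TGFβ iTreg replicate 1 the T cell identity list in RA+VitC against TGFβ iTreg (0.11) missed the threshold. Counted per gene and comparison, DESeq2 lost 21 calls of genes the rule takes and gave no adjusted p for 2, and thinning lost 34. Without 1 library, 23 and 11 were lost for replicates 2 and 1 of TGFβ iTreg, 17 and 9 for replicates 1 and 2 of RA+VitC iTreg, 11 for naive replicate 2 and at most 5 for the others. Nearest transcription start lost 15 beside those that turned. Over transcript regions 27 were lost in the same direction and 10 turned sign, all but Stk31 and Ifng against Treg without a call. Over regions that overlap a transcript, which leave out distal regions by construction, log2 fold changes turned sign for Stk31 (-0.48) and Icos (-0.026) in Treg against naive cells, Aldh1a2 (-0.43) and Tgm2 (-0.078) in TGFβ iTreg and Gpr15 (-0.001) in RA+VitC iTreg against naive cells, Ctla4 (-0.064) in RA+VitC against TGFβ iTreg, Ifng (-0.53) and Id2 (-0.11) in TGFβ iTreg against Treg, and Stk31 (1.87) and Ccr3 (-0.077) in RA+VitC iTreg against Treg. With loess offsets Ikzf2 (-0.062) and Ctla4 (-0.043) turned in RA+VitC against TGFβ iTreg. By nearest transcription start, which moves regions between neighbouring genes by construction, Cebpb (-0.084) turned in Treg against naive cells, Dnmt3l in TGFβ iTreg (-0.055) and RA+VitC iTreg (-0.14) against naive cells and in both against Treg (-0.26 and -0.35), Gadd45a (0.13) in RA+VitC iTreg against naive cells, Foxp3 (-0.42) in RA+VitC against TGFβ iTreg, and Foxp3 (1.53) and Ikzf4 (0.31) in TGFβ iTreg against Treg.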

Other observations

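The lists in this part were added after genes such as Isg15 and Irf9 had been noticed. The loess offsets and thinning were added after the library totals and the trend with abundance were seen. The mixture test and its matched form were chosen after the axis result was seen. The bounds of the other tests were set before their results, but the loess result was read as open after it was seen. Interferon-stimulated genes, without the 5 noticed first, carried less 5hmC in both iTreg groups than in naive cells. In TGFβ iTreg 16 of 36 fell and 5 rose (camera adjusted p = 0.0045; adjusted p = 0.11 with an estimated correlation), with Rtp4 at -0.99, the immunoproteasome subunit Psmb9 at -0.90 and Trim25 at -0.82. In RA+VitC iTreg 20 fell and 5 rose (adjusted p = 0.0047; adjusted p = 0.11 with an estimated correlation), with Rtp4 at -1.54, while Ifitm1 was higher in both groups (2.53 and 2.36). Against Treg, 13 fell and 6 rose in TGFβ iTreg and 14 fell and 5 rose in RA+VitC iTreg (camera adjusted p = 0.027 for each, and 0.13 with an estimated correlation). In Treg against naive cells 14 fell and 3 rose, and the list did not pass (camera adjusted p = 0.12).

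Cell cycle genes rose in 22 of 35 and fell in 3 in RA+VitC iTreg against naive cells (adjusted p = 0.0056; adjusted p = 0.13 with an estimated correlation), with Ccna2 at 1.57, Cdk6 at 1.26, Cdk1 at 1.14 and Mki67 at 1.01 (SE 0.07). In TGFβ iTreg 12 rose and 3 fell, and the list did not pass (adjusted p = 0.12), so the prediction for both groups against naive cells was not met. Against TGFβ iTreg, RA+VitC iTreg had 9 higher and 1 lower (adjusted p = 0.015; adjusted p = 0.13 with an estimated correlation), the lower one being Cdkn1a, an inhibitor of cell division (-0.75, SE 0.15). Against Treg, 16 rose and 3 fell in TGFβ iTreg (camera adjusted p = 0.019, and 0.13 with an estimated correlation). In RA+VitC iTreg 24 rose and 1 fell (camera adjusted p = 0.00038, and 0.11 with an estimated correlation). In Treg against naive cells 4 rose and 10 fell, and the list did not pass (camera adjusted p = 0.28). Glycolysis genes rose in 10 and fell in 5 of 22 in TGFβ iTreg and rose in 8 and fell in 5 in RA+VitC iTreg, with hexokinase Hk2 at 1.62 and 2.17, and the list did not pass (adjusted p = 0.33 and 0.28).

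More regions were higher than lower in RA+VitC iTreg against TGFβ iTreg (69.9% of calls). With loess offsets 55% were higher, the upper bound set beforehand for a trend with abundance as the cause. The result was read as open only after it was seen. These offsets centre the fold changes at every abundance, so they would also take away a gain in abundant regions. A trend with abundance from weaker enrichment in TGFβ iTreg therefore cannot be told apart from such a gain. In the fifth of regions most enriched over input in the iTreg pull-downs, 25.4% of the calls were lower, 1516 of 5972, over the bound set. This argues against dilution of a common profile by background reads in TGFβ iTreg as the source of all calls. Dilution on top of differences in both directions could still give the excess of higher regions, so it stays open as the cause of that excess. The fifth was also chosen on the iTreg pull-downs themselves. A difference in depth cannot be told apart, because at equal depth 59.5% were higher, between the bounds set. The excess of higher regions is therefore not read as more 5hmC with RA and VitC.

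RA+VitC iTreg lay nearer than TGFβ iTreg to Treg on the axis of regions that separate Treg from naive cells. At equal depth the difference was 0.225 over regions called anew in the thinned reads, and 0.183 over the regions called at full depth. Both are over the bound of 0.1, which argues against depth as the whole cause. Mixing RA+VitC iTreg reads with input reads came within 0.006 of TGFβ iTreg (SD 0.0082), but only at 100% input. A mixture matched on the share of reads in the strongest regions, 24.2% input, left a gap of 0.14 (SD 0.008), against 0.183 without input reads. The matched form was added after the smallest gap was seen and assumes that TGFβ iTreg share the RA+VitC iTreg profile, so background reads stay open as an explanation, as the inputs themselves lie at -0.30. That RA and VitC move iTreg 5hmC towards that of Treg is a hypothesis, which counts of the spiked amplicons or more replicates could test.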
